A study of Mus musculus with 4 samples.

How the data were processed

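The series holds ribosome profiling of Neuro2a cells, a mouse neuroblastoma line. Per the labels' protocols, cells were lysed in the presence of cycloheximide, which stalls elongating ribosomes, and each cleared lysate was divided into a total and an IP part. The total part was digested with micrococcal nuclease and its ribosomes were pelleted through a sucrose cushion. The IP part was digested while bound to beads with an antibody to the C-terminal part of Ebp1, washed, and extracted directly. Cushion, immunoprecipitation and the setting of the digestion therefore differ between the groups together. A mock immunoprecipitation was not analysed here. The 4 libraries form 2 groups of 2, which the series' design text calls biological replicates; whether they came from cultures grown separately is not stated in the sources used here, and if not, p-values measure only the spread between these samples.

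The deposited table lists 20419 mRNA genes with reads and RPKM for each library, per the file headers. The submitters' processing notes name cutadapt, Bowtie2 and TopHat2, without versions, and the mouse build mm10. The reads per gene that the authors deposited are estimated counts that need not be whole. Of the 20419 listed genes, those without a read included, between 14.0 and 25.5% per library had a value that is not a whole number. How the fractions arose is not given in the sources used here. The RPKM values that the authors deposited were used only for checks: the reads listed made up between 45.2 and 52.8% of the library total that the RPKM values imply, and 26 genes have an empty RPKM. The depth was 9707373, 9856225, 6451174 and 14454598 listed reads in IP replicates 1 and 2 and total replicates 1 and 2. Footprints have no molecular identifiers in the sources used here, so floors given from read counts cover counting error only.

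Gene names in the table lack a final g, e or n: 0 names end in one of these letters. For 417 genes the symbol was restored through the RefSeq accession of the row. A further 105 reference symbols, which would share a shortened name with a listed gene, are not used here. Coding length, coding GC content and position came from the GENCODE annotation of the same build, matched by RefSeq accession for 20305 genes and by symbol for 100; of the genes tested, 99.7% had a coding length. Mitochondrially encoded genes and non-coding RNAs were not analysed here.

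Counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, default low-count filter, which kept 11099 genes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design fixed before the data were examined has the group alone, with 2 residual degrees of freedom. The fixed alternative adds the replicate number as a block. The pairing comes from the labels' protocols, which divide each replicate's lysate. It was checked in the data. The deviations of same-numbered libraries from their group means had a Pearson correlation of 0.624 across genes. The first principal component (54.1% of the variance) separated the replicate numbers and the second (35.7%) separated IP from total. The split was not clean: on the first component IP also lay below total within each replicate (-35.5 against -9.90, and 8.78 against 36.6). In log2 CPM, IP replicate 1 correlated with IP replicate 2 (Pearson 0.975) a little more than with total replicate 1 (0.971). IP replicate 2 correlated most with total replicate 2 (0.981). Since the block changes the count of calls, blocked values stand beside the group-only result. The SE given with a log2 fold change is that of the block, derived from the F statistic. Its variance is borrowed mostly from other genes (44.0 prior degrees of freedom, against 1 residual degree of freedom). The SE and p of a gene therefore do not measure how far its own pairs differ. Other alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile normalization, no filter, a filter of 10 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the omission of histones, and the omission of each library in turn. Chosen after seeing the data were a GC correction (a natural spline of 5 degrees of freedom on coding GC content in each library, used as an offset), its combination with the block, and the block with other tools, without the filter and with fractional counts.

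Before the data were examined, 37 gene lists were fixed, and the 33 with at least 5 tested members were tested with camera in limma, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over lists. The lists of mitochondrially encoded proteins, non-coding RNAs, glial markers (4 members tested) and fibroblast and macrophage markers (1 member tested) were too small. With an estimated correlation none of the 18 called lists passed (adjusted p from 0.419 to 0.549), nor did they with the replicate block and an estimated correlation (0.523 to 0.583). A simulated list of 40 genes shifted by 0.4 (log2) did not pass with the group alone and an estimated correlation either (adjusted p = 0.166). Not passing with an estimated correlation therefore does not tell whether a list is shifted. Where the estimated correlation lies far above the preset, as for histones (0.755) and ER chaperones (0.441), the preset p-values may be too small. The rotation test fry, which asks whether a list's genes move on balance one way, passed lysosomal hydrolases (adjusted p = 0.0229) and none of the other called lists (0.0617 to 0.393); with the replicate block it passed none of the called lists (adjusted p from 0.207 to 0.232). The same 18 lists were called with the block and the preset correlation. The number of members passing when adjusted over the list alone stands beside the counts over all genes.

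The genes named were chosen by a rule fixed before the data were examined. It names Pa2g4; the 12 largest changes in each direction among genes past the threshold with at least 10 CPM and the same sign in both pairs, or, where fewer than 5 pass, the 5 with the smallest p in that direction; up to 4 members with the smallest p of each list; and the 5 genes of highest mean CPM. The second part leaves out predicted genes (Gm followed by digits, or names ending in Rik). Since no gene passed with the group alone, the second part was also applied to the fit with the replicate block, a choice made after seeing the data. Of the up to 4 members of each list that the rule gives, those named in the text are a part. Some genes that the rule gives are not reported here.

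The tests were checked on simulated counts drawn from the means, library sizes and dispersion trend of the data, with 200 genes changed. The replicate effect was the one fitted by the block, the same in IP and total, and each change was the same in both pairs. The counts thus follow the block's own model. Its recovery and few false calls follow largely from that setting and do not check its calls in the data. With the replicate effect of the data, the group-only design recovered 0 of 100 genes changed 1.5-fold and 0 of 100 changed 2-fold over 10989 genes, while the block recovered 70 and 98 and called 8 of 10789 unchanged genes. Without a replicate effect the group-only design recovered 74 and 100 over 10986 genes. With a GC trend drawn in, the block with GC correction recovered 67 and 98 over 11019 genes. It called 0 of 10819 unchanged ones, against 930 without the correction. The trend drawn in had the same spline form that the correction removes, so that 0 was largely fixed in advance. A simulated list of 40 genes shifted by 0.4 (log2) was called with the preset correlation (adjusted p = 2.48e-47) but not with an estimated one (adjusted p = 0.166), and 0 of 40 unshifted random lists were called; random lists lack the co-regulation of real ones. A class of genes shifted by -0.2 came out at -0.196, and an unshifted one at 0.012.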

Results

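Ribosome-protected mRNA fragments (footprints) were sequenced from Neuro2a cells, a mouse neuroblastoma line, in 4 libraries. 2 libraries came from ribosomes recovered on beads carrying an antibody to the C-terminal part of Ebp1 (IP), a ribosome-associated protein encoded by Pa2g4, and 2 came from the total ribosome pool of the matching lysates (total). The reads listed over genes numbered 9707373 in IP replicate 1, 9856225 in IP replicate 2, 6451174 in total replicate 1 and 14454598 in total replicate 2. A count of 3 reads corresponded to between 0.208 and 0.465 CPM (reads scaled to a common library size) in these libraries. The 10 most abundant genes held between 5.00 and 5.79% of the reads of a library. Eef1a1, which encodes a translation elongation factor, was the most abundant, with 12036 ± 605 CPM in total and 10546 ± 910 CPM in IP (mean ± SD, n = 2 each). Other genes among the most abundant were Hspa8, Hsp90ab1 and Actb, of which Hspa8 (log2 fold change -0.44 ± 0.07 SE, GC-corrected -0.33) and Actb (-0.48 ± 0.08, GC-corrected -0.64) were called lower in IP with the replicate block and Hsp90ab1 (adjusted p = 0.0856) was not. Eef1a1 was called lower with the block (adjusted p = 0.0286) and not with GC correction as well (adjusted p = 0.370). Eef1a1 had a group-only log2 fold change of -0.19, against -0.10 without IP replicate 1, and pair ratios of -0.23 and -0.16.

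The comparison of IP with total asks which coding sequences are over- or under-represented among the ribosomes that the Ebp1 antibody recovers. Footprints on genes of endoplasmic reticulum (ER) chaperones, lysosomal hydrolases, secreted and matrix proteins and cell adhesion molecules were lower in IP in both replicates, with list medians between -0.56 and -0.30 on the log2 scale. Footprints on histone genes were higher in both replicates, with list medians of 0.71 and 0.84. These 5 lists passed camera's test with a preset correlation and did not with an estimated correlation (adjusted p from 0.419 to 0.488). In simulated counts a random list shifted by 0.4 (log2) did not pass camera with an estimated correlation either (adjusted p = 0.166). Not passing therefore does not tell whether a list is shifted. The estimated correlation was 0.755 for histones and 0.441 for ER chaperones, against the preset of 0.01. Their p-values with the preset may thus be too small. For secreted and matrix proteins, cell adhesion molecules and lysosomal hydrolases it was 0.014, -0.009 and -0.029. Without regard to the pairing of the replicates, no single gene passed the test: edgeR's quasi-likelihood test called 0 of 11099 genes higher and 0 lower at an adjusted p of 0.05, the smallest adjusted p being 0.236. At an unadjusted p under 0.05 there were 939 genes higher and 777 lower, where 555 in all are expected by chance; limma-voom called 0 genes in either direction and DESeq2 116 higher and 74 lower. Each replicate's lysate was divided into its IP and total sample, and with that pairing in the model (the replicate block) 1874 genes were called higher and 1870 lower, of which 179 and 31 differed at least 2-fold. Of all genes tested, 76.1% had the same sign in both pairs. The block leaves 1 residual degree of freedom, and single-gene calls below refer to it. Their SEs and p-values rest mostly on variance shared across genes (44.0 prior degrees of freedom), so a small SE can stand beside unlike pairs.

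GC content of the coding sequence moved with the comparison. Its Spearman correlation with the log2 fold change across genes, which are not independent replicates, was 0.585 (0.461 in pair 1 and 0.610 in pair 2). The median coding GC content was 58.1% in genes called higher with the replicate block, 46.9% in genes called lower and 52.8% in those not called. Libraries of the same group also differed along GC content, with correlations of 0.365 for IP replicate 1 minus IP replicate 2 and 0.407 for total replicate 1 minus total replicate 2. With a GC correction added to the block after seeing the data, 875 genes were called higher and 889 lower; 720 and 689 of these were also called without the correction, and 0 were called in opposite directions. Each gene list below is therefore given with its GC-corrected counts and median, and each gene with its GC-corrected log2 fold change, both from the fit with the block. Where leaving out 1 library moved a value called with the block or by camera by over 1.5 times, the group-only values without that library are given. Leaving out a library breaks its pair, so that such a move can also come from a difference between the replicates that cancels within pairs.

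**Figure D1:**
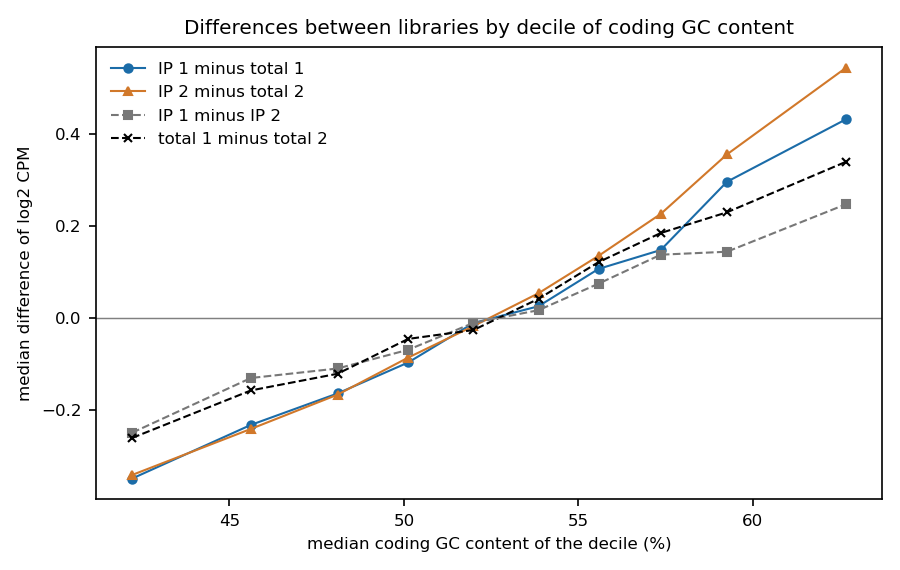
Median difference of log2 CPM between 2 libraries (vertical axis) in each decile of tested genes by coding GC content (horizontal axis, percent); solid lines are IP minus total within a replicate, dashed lines are 2 libraries of the same group. The IP minus total medians run from -0.35 and -0.34 in the lowest decile to 0.43 and 0.55 in the highest, and the dashed lines run the same way from -0.25 and -0.26 to 0.25 and 0.34.

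Pa2g4, the gene of Ebp1 itself (mm10 chromosome 10, 128557766 to 128565987, minus strand), had 727 ± 101 CPM in total and 563 ± 83.4 CPM in IP (mean ± SD, n = 2 each). Its log2 fold change was -0.37 with the group alone (adjusted p = 0.363) and -0.37 ± 0.09 (SE) with the replicate block (adjusted p = 8.70e-04), and -0.20 with GC correction as well (adjusted p = 0.125), which does not pass. It was lower in IP in both pairs. The group-only value was -0.23 without IP replicate 1 and -0.21 without total replicate 2, and the log2 ratios within pairs were -0.38 and -0.36.

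Genes of ER chaperones and folding enzymes had a median log2 fold change of -0.51 over 37 tested members (camera adjusted p = 2.27e-08, and adjusted p = 0.488 with an estimated correlation), and of -0.38 with GC correction and the block. In the blocked fit 2 members were called higher and 24 lower (0 and 19 with GC correction). The median was -0.30 without IP replicate 1. Hsp90b1, which encodes the ER form of Hsp90 (chromosome 10, 86690209 to 86705509, minus strand), had 2152 ± 559 CPM in total and 1050 ± 327 CPM in IP (mean ± SD, n = 2 each), a log2 fold change of -1.05 ± 0.08 (SE, adjusted p = 7.07e-13 with the block) and of -0.74 with GC correction. Other members called lower, with log2 fold change ± SE, were Canx (-0.91 ± 0.08, GC-corrected -0.67), Hspa5 (-0.89 ± 0.09, GC-corrected -0.72) and Uggt1 (-0.75 ± 0.09, GC-corrected -0.57), which encode calnexin, the chaperone BiP and a glycoprotein folding sensor. The ER translocon and membrane insertion machinery had a median log2 fold change of -0.18 over 40 tested members (camera adjusted p = 0.00934, and adjusted p = 0.549 with an estimated correlation), and of -0.13 with GC correction and the block. Of these members 5 were called higher and 17 lower with the replicate block, and 2 and 12 once GC content was also corrected for. With 1 library omitted, the median was -0.27 without IP replicate 2 and -0.06 without total replicate 2. Its call is lost without IP replicate 1 (adjusted p = 0.141) or without total replicate 2 (adjusted p = 0.199). Stt3a (-0.73 ± 0.09, GC-corrected -0.49) and Magt1 (-0.67 ± 0.13, GC-corrected -0.46), both subunits of oligosaccharyltransferase, were called lower, whereas Sec61b (0.87 ± 0.14, GC-corrected 0.68), a translocon subunit with a single membrane segment near its C-terminus, was called higher, also with GC correction (adjusted p = 0.00463).

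Genes of secreted and matrix proteins had a median log2 fold change of -0.47 over 62 tested members (camera adjusted p = 2.67e-05, and adjusted p = 0.419 with an estimated correlation), and of -0.59 with GC correction and the block. Members called with the block numbered 2 higher and 23 lower, and 1 higher and 31 lower after GC correction. Leaving out 1 library moved the median to -0.08 without total replicate 1. Scg2 (-0.81 ± 0.09, GC-corrected -0.71) and Scg3 (-0.97 ± 0.09, GC-corrected -0.71), which encode secretogranins of dense-core vesicles, and Vcan (-1.14 ± 0.13, GC-corrected -0.86), Fbln2 (-0.67 ± 0.10, GC-corrected -0.93) and Sparc (-0.97 ± 0.21, GC-corrected -1.14), which encode matrix proteins, were called lower. Sparc differed between replicates, with 17.2 ± 15.0 CPM in total and 8.87 ± 7.99 CPM in IP (mean ± SD, n = 2 each), and its group-only log2 fold change was -2.37 without IP replicate 1, -0.18 without IP replicate 2, 0.43 without total replicate 1 and -1.63 without total replicate 2. Within pairs its log2 ratios were -0.93 and -0.99. Vcan had a group-only log2 fold change of -1.16, against -0.68 without IP replicate 1, -1.85 without IP replicate 2 and -0.35 without total replicate 2, and pair ratios of -1.07 and -1.18. Gdf15 (0.82 ± 0.14, GC-corrected 0.20), a secreted growth factor, was called higher with the block and not with GC correction as well (adjusted p = 0.343). Lysosomal hydrolases had a median log2 fold change of -0.46 over 34 tested members (camera adjusted p = 1.14e-08, and adjusted p = 0.419 with an estimated correlation), and of -0.42 with GC correction and the block. The replicate block called 0 of them higher and 20 lower, and 0 and 16 with GC correction as well. Psap, the precursor of the saposins, had 834 ± 53.9 CPM in total and 484 ± 6.83 CPM in IP (mean ± SD, n = 2 each). Psap (-0.78 ± 0.09, GC-corrected -0.87) and Ctsd (-0.62 ± 0.09, GC-corrected -0.63) were called lower, the last encoding cathepsin D.

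Cell adhesion molecules had a median log2 fold change of -0.32 over 58 tested members (camera adjusted p = 5.44e-04, and adjusted p = 0.419 with an estimated correlation), and of -0.43 with GC correction and the block. In the blocked fit 7 members were called higher and 23 lower (1 and 24 with GC correction). Itgb1 (-0.89 ± 0.08, GC-corrected -0.58) and Itga1 (-0.89 ± 0.10, GC-corrected -0.67), integrin subunits, and Nrcam (-1.11 ± 0.18, GC-corrected -0.96) and Pcdh1 (-0.66 ± 0.09, GC-corrected -0.87) were called lower. Axon guidance ligands and receptors had a median log2 fold change of -0.17 over 36 tested members (camera adjusted p = 0.0227, and adjusted p = 0.468 with an estimated correlation), and of -0.36 with GC correction and the block. Of these members 2 were called higher and 10 lower with the replicate block, and 0 and 13 once GC content was also corrected for. The median was -0.25 without IP replicate 1, -0.03 without total replicate 1 and -0.36 without total replicate 2. Nrp1 (-0.81 ± 0.10, GC-corrected -0.71), Neo1 (-0.80 ± 0.09, GC-corrected -0.68) and Plxnb2 (-0.57 ± 0.10, GC-corrected -0.73), all receptors, were called lower; the list's call is lost without total replicate 1 (median -0.03, adjusted p = 0.196). Solute carriers had a median log2 fold change of -0.13 over 185 tested members (camera adjusted p = 0.0138, and adjusted p = 0.484 with an estimated correlation), and of -0.15 with GC correction and the block. Members called with the block numbered 11 higher and 40 lower, and 2 higher and 31 lower after GC correction. Slc44a2 (-0.82 ± 0.13, GC-corrected -0.80) and Slc12a9 (-0.68 ± 0.14, GC-corrected -1.03) were called lower. The call of this list is lost without IP replicate 1 (adjusted p = 0.0809) or without total replicate 2 (adjusted p = 0.102). Cholesterol and lipid synthesis genes had a median log2 fold change of -0.26 over 33 tested members (camera adjusted p = 0.00934, and adjusted p = 0.423 with an estimated correlation), and of -0.24 with GC correction and the block. The replicate block called 3 of them higher and 15 lower, and 1 and 12 with GC correction as well. Scd1 (-0.47 ± 0.10, GC-corrected -0.60), which encodes a fatty acid desaturase of the ER membrane, was called lower and Srebf2 (0.83 ± 0.09, GC-corrected 0.56), a transcription factor of the pathway, higher.

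**Figure D2:**
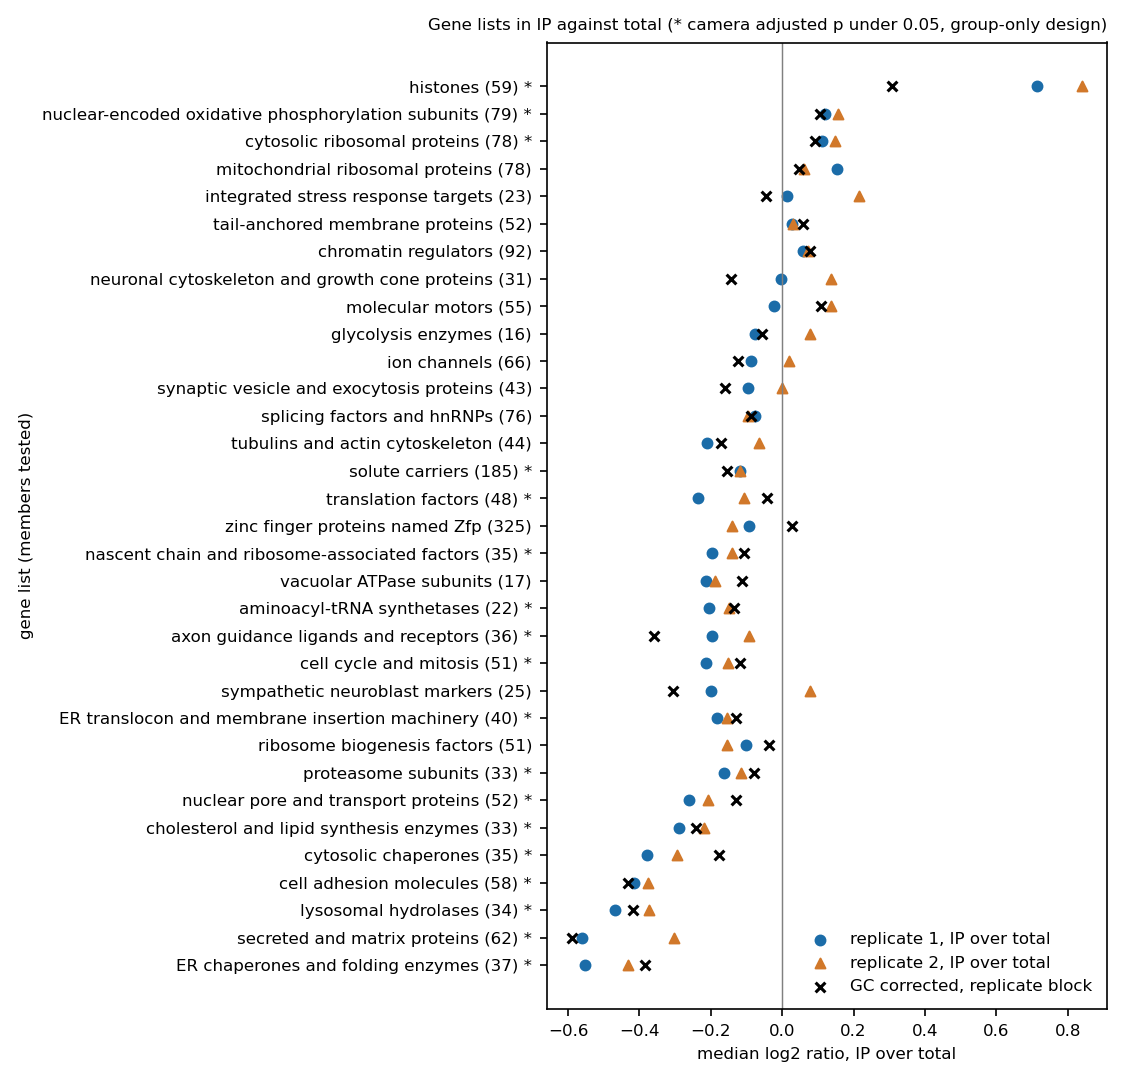
Median log2 ratio of IP over total (horizontal axis) of each gene list with at least 5 tested members (vertical axis, members tested in brackets); circles and triangles are replicates 1 and 2, crosses the fit with the replicate block and GC correction, and asterisks mark the 18 lists called by camera with a preset correlation, none of which is called with an estimated correlation. ER chaperones, secreted proteins, lysosomal hydrolases and adhesion molecules lie between -0.59 and -0.30 by all 3 symbols, and histones between 0.31 and 0.84.

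Histone genes had a median log2 fold change of 0.86 over 59 tested members (camera adjusted p = 3.23e-21, and adjusted p = 0.484 with an estimated correlation), and of 0.31 with GC correction and the block. In the blocked fit 52 members were called higher and 0 lower (24 and 4 with GC correction). With 1 library omitted, the median was 0.46 without IP replicate 1 and 0.40 without total replicate 2. They took 3.29 and 2.06% of the listed reads in IP replicates 1 and 2, and 2.05 and 1.41% in total replicates 1 and 2. The list's median coding GC content was 66.0%. H3c1 (1.27 ± 0.11, GC-corrected 0.64), H3c11 (1.25 ± 0.10, GC-corrected 0.61), H3c6 (1.34 ± 0.11, GC-corrected 0.69), H4c14 (1.40 ± 0.10, GC-corrected 0.92) and H2bc1 (1.59 ± 0.13, GC-corrected 1.33) were called higher with the block and with GC correction. H4c14 had a group-only log2 fold change of 1.40, against 0.89 without IP replicate 1, and pair ratios of 1.38 and 1.41. Many histone genes are near-identical copies, so the value of a single copy is uncertain where reads were divided among them. Cytosolic ribosomal protein genes had a median log2 fold change of 0.11 over 78 tested members (camera adjusted p = 0.0118, and adjusted p = 0.488 with an estimated correlation), and of 0.09 with GC correction and the block. Of these members 31 were called higher and 10 lower with the replicate block, and 22 and 8 once GC content was also corrected for. Leaving out 1 library moved the median to 0.18 without IP replicate 1 and 0.19 without total replicate 2. Rpl9 (0.66 ± 0.09, GC-corrected 0.78) and Fau (0.85 ± 0.09, GC-corrected 0.57) were called higher and Rpl35a (-0.58 ± 0.09, GC-corrected -0.45) lower. Reads of these genes can be shared with processed pseudogenes. The list's call is lost without IP replicate 2 (adjusted p = 0.198) or without total replicate 1 (adjusted p = 0.267). Nuclear-encoded subunits of oxidative phosphorylation had a median log2 fold change of 0.12 over 79 tested members (camera adjusted p = 0.0126, and adjusted p = 0.423 with an estimated correlation), and of 0.10 with GC correction and the block. Members called with the block numbered 21 higher and 6 lower, and 12 higher and 1 lower after GC correction. The median was 0.06 without IP replicate 2. Ndufb11 (0.65 ± 0.11, GC-corrected 0.55) and Atp5g1 (0.70 ± 0.10, GC-corrected 0.53) were called higher. Without IP replicate 2 the call of this list is lost (adjusted p = 0.117).

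Cytosolic chaperones had a median log2 fold change of -0.31 over 35 tested members (camera adjusted p = 4.41e-07, and adjusted p = 0.484 with an estimated correlation), and of -0.18 with GC correction and the block. The replicate block called 1 of them higher and 22 lower, and 1 and 10 with GC correction as well. With 1 library omitted, the median was -0.46 without IP replicate 2 and -0.46 without total replicate 1. Hsp90aa1 (-0.71 ± 0.08, GC-corrected -0.41), Pfdn4 (-0.79 ± 0.10, GC-corrected -0.56) and St13 (-0.54 ± 0.09, GC-corrected -0.44) were called lower. Nuclear pore and transport proteins had a median log2 fold change of -0.24 over 52 tested members (camera adjusted p = 1.74e-05, and adjusted p = 0.488 with an estimated correlation), and of -0.13 with GC correction and the block. In the blocked fit 3 members were called higher and 25 lower (4 and 15 with GC correction). Nup210, a pore protein with a membrane segment, and the transport receptors Ipo11 and Cse1l were called lower, with values of Nup210 (-0.80 ± 0.10, GC-corrected -0.91), Ipo11 (-0.73 ± 0.09, GC-corrected -0.43) and Cse1l (-0.64 ± 0.09, GC-corrected -0.30). Proteasome subunits had a median log2 fold change of -0.21 over 33 tested members (camera adjusted p = 0.0113, and adjusted p = 0.484 with an estimated correlation), and of -0.08 with GC correction and the block. Of these members 2 were called higher and 14 lower with the replicate block, and 1 and 4 once GC content was also corrected for. Leaving out 1 library moved the median to -0.11 without total replicate 2. Psmd12 (-0.51 ± 0.09, GC-corrected -0.30) was called lower; the list passes no longer with GC correction (adjusted p = 0.111) or without total replicate 2 (adjusted p = 0.0840). Cell cycle and mitosis genes had a median log2 fold change of -0.17 over 51 tested members (camera adjusted p = 5.44e-04, and adjusted p = 0.419 with an estimated correlation), and of -0.12 with GC correction and the block. Members called with the block numbered 4 higher and 22 lower, and 1 higher and 6 lower after GC correction. The list does not pass with GC correction (adjusted p = 0.111). Smc4 (-0.71 ± 0.09, GC-corrected -0.30) and Smc2 (-0.59 ± 0.09, GC-corrected -0.24), condensin subunits of 38.6 and 40.9% coding GC content, were called lower with the block, Smc2 not with GC correction as well (adjusted p = 0.0860).

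Translation factors had a median log2 fold change of -0.13 over 48 tested members (camera adjusted p = 0.0368, and adjusted p = 0.488 with an estimated correlation), and of -0.04 with GC correction and the block. The replicate block called 6 of them higher and 18 lower, and 5 and 3 with GC correction as well. This call is lost without the low-count filter (adjusted p = 0.0551), with the stricter filter (adjusted p = 0.0929), with GC correction and the block (adjusted p = 0.618) and on the omission of any 1 library (adjusted p from 0.0662 to 0.134). Eif2b1 (-0.71 ± 0.15, GC-corrected -0.59) was called lower and Eif6 (0.58 ± 0.12, GC-corrected 0.39) higher. Aminoacyl-tRNA synthetases had a median log2 fold change of -0.16 over 22 tested members (camera adjusted p = 0.00761, and adjusted p = 0.488 with an estimated correlation), and of -0.13 with GC correction and the block. In the blocked fit 0 members were called higher and 8 lower (0 and 2 with GC correction). The median was -0.31 without IP replicate 2 and -0.27 without total replicate 1. Rars (-0.81 ± 0.09, GC-corrected -0.59) was called lower. The list's call is lost without IP replicate 1 (adjusted p = 0.0837) or total replicate 2 (adjusted p = 0.0840). Nascent chain and ribosome-associated factors had a median log2 fold change of -0.15 over 35 tested members (camera adjusted p = 0.0227, and adjusted p = 0.488 with an estimated correlation), and of -0.11 with GC correction and the block. Of these members 3 were called higher and 12 lower with the replicate block, and 1 and 4 once GC content was also corrected for. The list does not pass with GC correction and the block (adjusted p = 0.210), nor without IP replicate 1 (adjusted p = 0.0742) or total replicate 2 (adjusted p = 0.240). Naa15 (-0.62 ± 0.09, GC-corrected -0.24), of an N-terminal acetyltransferase, and Srp54a (-0.47 ± 0.09, GC-corrected -0.11), of the signal recognition particle, were called lower with the block but not with GC correction (adjusted p = 0.0799 and 0.471), and Rnf10 (0.69 ± 0.10, GC-corrected 0.61), a ubiquitin ligase, was called higher with both. Rnf10 had a group-only log2 fold change of 0.70, against 0.46 without IP replicate 1, and pair ratios of 0.83 and 0.54.

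Of the 33 lists tested, 15 did not pass camera's test with the preset correlation. Counts here are of members called with the replicate block, and then with GC correction as well. Among membrane and vesicle lists these were tail-anchored membrane proteins (median 0.05, adjusted p = 0.352, 9 higher and 2 lower of 52, GC-corrected 5 and 3 with median 0.06), ion channels (median -0.02, adjusted p = 0.849, 9 higher and 11 lower of 66, GC-corrected 5 and 5 with median -0.13), synaptic vesicle and exocytosis proteins (median -0.08, adjusted p = 0.822, 6 higher and 6 lower of 43, GC-corrected 3 and 5 with median -0.16) and vacuolar ATPase subunits (median -0.16, adjusted p = 0.0725, 1 higher and 5 lower of 17, GC-corrected 0 and 2 with median -0.11). Among the remaining ones were mitochondrial ribosomal proteins (median 0.08, adjusted p = 0.117, 23 higher and 8 lower of 78, GC-corrected 4 and 2 with median 0.05), tubulins and actin cytoskeleton (median -0.12, adjusted p = 0.338, 9 higher and 15 lower of 44, GC-corrected 4 and 15 with median -0.17) and neuronal cytoskeleton and growth cone proteins (median 0.03, adjusted p = 0.373, 7 higher and 5 lower of 31, GC-corrected 4 and 9 with median -0.14). Not passing either were zinc finger proteins named Zfp (median -0.14, adjusted p = 0.126, 40 higher and 65 lower of 325, GC-corrected 15 and 7 with median 0.03) and ribosome biogenesis factors (median -0.18, adjusted p = 0.121, 9 higher and 19 lower of 51, GC-corrected 5 and 6 with median -0.04). To them belonged also splicing factors and hnRNPs (median -0.11, adjusted p = 0.373, 13 higher and 25 lower of 76, GC-corrected 8 and 15 with median -0.09), glycolysis enzymes (median 0.00493, adjusted p = 0.849, 3 higher and 0 lower of 16, GC-corrected 0 and 2 with median -0.06) and integrated stress response targets (median 0.07, adjusted p = 0.154, 7 higher and 2 lower of 23, GC-corrected 1 and 3 with median -0.04). The mean differed in sign from the median for ion channels (0.0111) and synaptic vesicle and exocytosis proteins (2.68e-04), for both of which camera's direction was down. Some of these lists passed when 1 library was left out. Glycolysis enzymes were then lower without IP replicate 1 (median -0.14) or total replicate 2 (-0.23) and higher without total replicate 1 (0.28). Zinc finger genes (-0.21 and -0.22) and ribosome biogenesis factors (-0.19 and -0.21) passed without IP replicate 2 or total replicate 1, stress response targets without IP replicate 1 (0.17) or total replicate 2 (0.22), and vacuolar ATPase subunits without IP replicate 1 (-0.23). Among tail-anchored proteins, whose single membrane segment lies at the C-terminus, Vamp2 (1.28 ± 0.20, GC-corrected 1.07), Tomm5 (0.72 ± 0.18, GC-corrected 0.76) and Fkbp8 (0.66 ± 0.10, GC-corrected 0.25) were called higher, Fkbp8 not with GC correction (adjusted p = 0.0985). Of the synaptic list, Syt1 (-0.58 ± 0.10, GC-corrected -0.49) was called lower and Unc13a (0.54 ± 0.10, GC-corrected 0.35) higher. Of the ion channels Piezo1 (-0.51 ± 0.10, GC-corrected -0.76) was called lower. Prph (0.76 ± 0.09, GC-corrected 0.33), Sptbn1 (0.69 ± 0.11, GC-corrected 0.76) and Arpc1b (0.63 ± 0.11, GC-corrected 0.38) of the cytoskeletal lists were called higher and Capzb (-0.62 ± 0.09, GC-corrected -0.62) lower. Srrm2 (0.74 ± 0.09, GC-corrected 0.76), Nop16 (0.76 ± 0.12, GC-corrected 0.71), Atf4 (0.45 ± 0.08, GC-corrected 0.48) and Zfp593 (1.06 ± 0.14, GC-corrected 0.56) were called higher. Lower were Utp3 (-0.59 ± 0.12, GC-corrected -0.49), Zfp329 (-1.38 ± 0.24, GC-corrected -1.10) and Atp6ap1 (-0.56 ± 0.11, GC-corrected -0.57). Vamp2 had a group-only log2 fold change of 1.38, against 0.92 without IP replicate 1, and pair ratios of 1.94 and 0.73. Unc13a had a group-only log2 fold change of 0.55, against 0.36 without IP replicate 1, and pair ratios of 0.62 and 0.45. Sptbn1 had a group-only log2 fold change of 0.72, against 0.35 without IP replicate 2, and pair ratios of 0.29 and 1.07. Nop16 had a group-only log2 fold change of 0.74, against 0.47 without total replicate 1, and pair ratios of 0.88 and 0.65.

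A further 3 lists did not pass with the group alone and passed camera's test with GC correction. Molecular motors had a median of 0.03 with the group alone (adjusted p = 0.166), -0.02 in pair 1, 0.14 in pair 2, 0.04 with the block, and 0.11 with GC correction as well (adjusted p = 0.0138, and adjusted p = 0.537 with an estimated correlation). Members called with the block numbered 19 higher and 12 lower, and 10 higher and 1 lower after GC correction. Chromatin regulators had a median of 0.04 with the group alone (adjusted p = 0.153), 0.06 in pair 1, 0.07 in pair 2, 0.05 with the block, and 0.08 with GC correction as well (adjusted p = 0.0287, and adjusted p = 0.506 with an estimated correlation). The replicate block called 23 of them higher and 15 lower, and 17 and 3 with GC correction as well. Sympathetic neuroblast markers had a median of -0.18 with the group alone (adjusted p = 0.423), -0.20 in pair 1, 0.08 in pair 2, -0.09 with the block, and -0.30 with GC correction as well (adjusted p = 6.51e-06, and adjusted p = 0.506 with an estimated correlation). In the blocked fit 4 members were called higher and 8 lower (0 and 9 with GC correction). Of these medians, that of the neuroblast markers was -0.08 without total replicate 1, and that of chromatin regulators 0.11 without IP replicate 1 and 0.12 without total replicate 2. Molecular motors also passed without IP replicate 1 (adjusted p = 0.0156), and their median was 0.14 without total replicate 1 and -0.02 without total replicate 2. Dync1h1 (0.85 ± 0.09, GC-corrected 0.82), Chd4 (0.50 ± 0.08, GC-corrected 0.51) and Kdm6b (0.90 ± 0.10, GC-corrected 0.49), which encode the dynein heavy chain, a chromatin remodeller and a histone demethylase, were called higher with the block and with GC correction. Chga, which encodes chromogranin A, was called lower (-0.64 ± 0.10, GC-corrected -0.94), and Hand2 (0.83 ± 0.10, GC-corrected 0.25), a transcription factor, higher with the block but not with GC correction (adjusted p = 0.114). Adjusted over the list alone with the group-only design, 23 histone genes, 8 lysosomal hydrolases, 7 secreted and matrix proteins, 6 ER chaperones, 6 cell adhesion molecules and 3 molecular motors passed. Adjusted over the list alone in the same way, 2 axon guidance genes, 2 cytosolic chaperones, 1 aminoacyl-tRNA synthetase, 1 splicing factor and 1 sympathetic neuroblast marker passed, and 0 members of the other 22 lists.

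Genes were ranked by size of change with the replicate block, predicted genes left out. The largest increases at a mean of at least 10 CPM were led by Synpo2, which encodes an actin-binding protein (chromosome 3, 123076519 to 123236149, minus strand). Synpo2 had 10.2 ± 4.23 CPM in total and 38.6 ± 6.58 CPM in IP (mean ± SD, n = 2 each). Its log2 fold change was 1.91 ± 0.16 (SE, adjusted p = 2.97e-12 with the block), GC-corrected 1.85. After it came Jph4 (1.74 ± 0.15, GC-corrected 1.11), Dbn1 (1.53 ± 0.24, GC-corrected 1.24), Ppp1r9b (1.51 ± 0.17, GC-corrected 0.99) and Myo18a (1.46 ± 0.13, GC-corrected 1.24). Next were Hnrnpa0 (1.42 ± 0.11, GC-corrected 0.64), Klhdc8b (1.40 ± 0.21, GC-corrected 0.99), Pusl1 (1.37 ± 0.14, GC-corrected 1.06) and Tbc1d16 (1.30 ± 0.16, GC-corrected 0.97), with the histone genes already named among them. Dbn1 encodes drebrin and Ppp1r9b spinophilin. Among the genes that the rule gives at a mean of at least 10 CPM, the largest decreases were those of Sez6l2 (-1.19 ± 0.12, GC-corrected -1.51), Vcan (-1.14 ± 0.13, GC-corrected -0.86), Nrcam (-1.11 ± 0.18, GC-corrected -0.96), Acta2 (-1.07 ± 0.12, GC-corrected -1.10) and Hsp90b1 (-1.05 ± 0.08, GC-corrected -0.74). They were followed by BC005561 (-0.98 ± 0.15, GC-corrected -0.58), Epm2aip1 (-0.98 ± 0.22, GC-corrected -0.88), Ace (-0.98 ± 0.17, GC-corrected -1.09), Enpp1 (-0.97 ± 0.14, GC-corrected -0.81), Scg3 (-0.97 ± 0.09, GC-corrected -0.71), Sparc (-0.97 ± 0.21, GC-corrected -1.14) and Zfp951 (-0.97 ± 0.20, GC-corrected -0.62). Leaving out 1 library, which breaks a pair, moved the group-only value of several of these genes by over 1.5 times. Dbn1 had a group-only log2 fold change of 1.89, against 0.11 without IP replicate 2, and pair ratios of 0.03 and 2.71. Ppp1r9b had a group-only log2 fold change of 1.59, against 0.68 without IP replicate 2, and pair ratios of 0.68 and 2.12. The block's SEs of Dbn1 (0.24) and Ppp1r9b (0.17) do not measure this spread between their pairs. Klhdc8b had a group-only log2 fold change of 1.46, against 0.94 without IP replicate 1, and pair ratios of 1.48 and 1.27. Tbc1d16 had a group-only log2 fold change of 1.41, against 0.74 without IP replicate 1, and pair ratios of 1.63 and 0.96. BC005561 had a group-only log2 fold change of -0.94, against -0.40 without IP replicate 1, -1.78 without IP replicate 2 and -0.52 without total replicate 2, and pair ratios of -1.38 and -0.70. Ace had a group-only log2 fold change of -0.95, against -1.77 without IP replicate 1, -0.41 without IP replicate 2, -0.15 without total replicate 1 and -1.48 without total replicate 2, and pair ratios of -0.96 and -0.97. Vcan was at -0.68 without IP replicate 1, -1.85 without IP replicate 2 and -0.35 without total replicate 2, with pair ratios of -1.07 and -1.18. Sparc was at -2.37 without IP replicate 1, -0.18 without IP replicate 2, 0.43 without total replicate 1 and -1.63 without total replicate 2, with pair ratios of -0.93 and -0.99. With the group alone, the smallest p-values belonged to Hnrnpa0, Kif26a, Wwc1, Mtcl1 and Myo18a among higher genes and to Sez6l2, Serinc1, Scg2, H13 and Itgb1 among lower genes, all at an adjusted p of 0.236 and not passing. Called with the block were Kif26a (1.25 ± 0.12, GC-corrected 0.74), Wwc1 (1.17 ± 0.11, GC-corrected 0.97) and Mtcl1 (1.24 ± 0.11, GC-corrected 0.80) as higher and Serinc1 (-0.88 ± 0.09, GC-corrected -0.66) and H13 (-0.91 ± 0.11, GC-corrected -1.12) as lower.

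**Figure D3:**
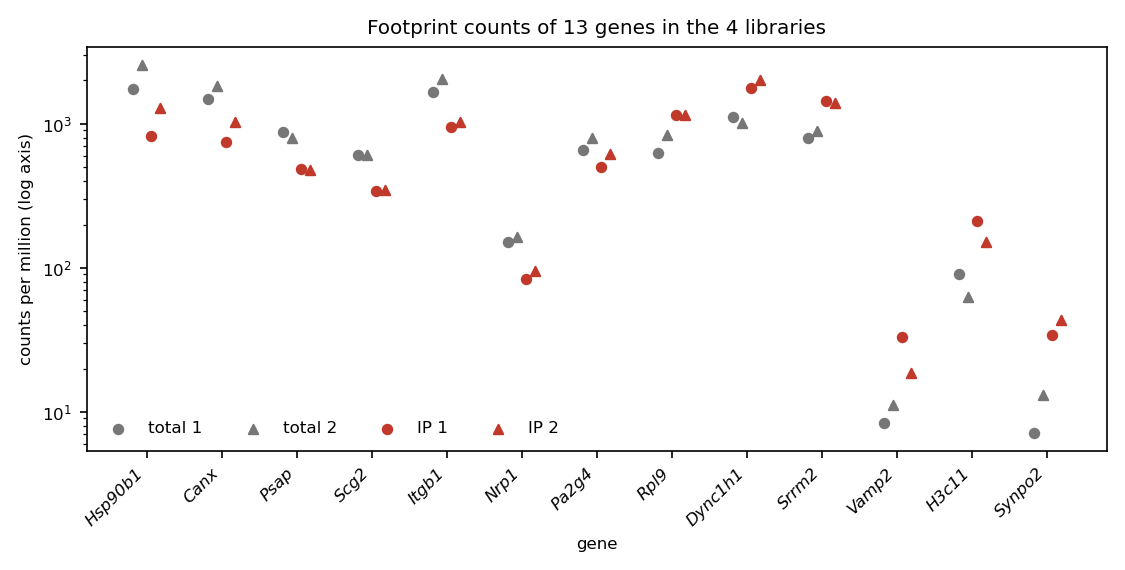
CPM (vertical axis, log scale) of 13 genes in each of the 4 libraries; grey points are total and red points IP, circles replicate 1 and triangles replicate 2. Within each replicate Hsp90b1, Canx, Psap, Scg2, Itgb1, Nrp1 and Pa2g4 are lower in IP and the other 6 are higher, from 7.18 to 33.9 CPM for Synpo2 in replicate 1.

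The relation of the log2 fold change to coding length was small. Spearman's rho across 11069 genes, which are not independent replicates, was -0.087 with the group alone, -0.085 in pair 1 and -0.070 in pair 2, longer coding sequences having lower ratios. With the replicate block and GC correction it was -0.044. Simulated data limited the reading of single-gene calls. The curve fitted to the observed GC trend was drawn into otherwise unchanged genes (Spearman correlation of GC content with log2 fold change 0.759, against 0.585 in the data). The replicate block then called 930 of 10819 of them, and 0 with GC correction as well. The correction removes a spline of the same form as the curve drawn in. That 0 therefore does not show that the correction clears the GC effect in the data.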

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

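Chosen after seeing the data were the GC correction, its combination with the replicate block, and the block with DESeq2, limma-voom, no filter and fractional counts. The count of genes called was 0 in either direction with DESeq2 size factors, upper-quartile normalization, no filter, the stricter filter, limma-voom, the omission of histones, and GC correction without the block. DESeq2's Wald test called 116 genes higher and 74 lower. The replicate block called 1874 higher and 1870 lower, and with GC correction 875 and 889. With the replicate block, DESeq2 called 691 and 831, limma-voom 1910 and 1922, edgeR without the filter 1982 and 1742, and edgeR on fractional counts 1854 and 1841. Leaving out 1 library gave between 0 and 283 genes higher and between 0 and 135 lower: 30 and 11 without IP replicate 1, 283 and 135 without IP replicate 2, and 0 without either total library; the library left alone in its group is then assumed to vary like the other group. In counts simulated with the replicate effect fitted by the block, the group-only design recovered 0 and the block 98 of 100 genes changed 2-fold. Such an effect is enough to leave the group-only design without calls. The counts were drawn from the block's own model, so they do not check the block's calls in the data. For the other settings the cause was not tested. The block changed no list's call by camera with the preset correlation, while the rotation test's call of lysosomal hydrolases (adjusted p = 0.0229) was lost with it (0.207). With GC correction and the block, 14 of the 18 called lists kept their call and direction, translation factors, nascent chain factors, proteasome subunits and cell cycle genes lost it, and 3 gained one; with an estimated correlation none passed in that fit (adjusted p of 0.506 or more). The correlation with coding length was -0.109 for the length of the longest transcript and -0.053 for genes of at least 10 CPM, against -0.087; the cause was not tested. Of the 99 genes named in the text, 98 passed with the block and 90 with the block and GC correction. DESeq2 gave an adjusted p for 88, of which 49 passed. These 99 are only a part of the genes that the rule gives and do not stand for all genes called. Of the block's 1874 higher and 1870 lower calls over all genes, 720 and 689 were kept with GC correction. Lists that gained a call when 1 library was left out were glycolysis enzymes (lower without IP replicate 1, adjusted p = 0.0258, or total replicate 2, 0.00798, and higher without total replicate 1, 0.0462), zinc finger proteins (lower without IP replicate 2, 0.0342, or total replicate 1, 0.00424), ribosome biogenesis factors (lower without the same, 0.0169 and 0.0149), molecular motors (higher without IP replicate 1, 0.0156), vacuolar ATPase subunits (lower without IP replicate 1, 0.0489) and integrated stress response targets (higher without IP replicate 1, 0.00115, or total replicate 2, 0.0206). Without the filter, mitochondrial ribosomal proteins passed (adjusted p = 0.0491). Reversals were few and the cause was not tested. Leaving out 1 library gave -2.37 to 0.43 for Sparc, -0.16 to 0.051 for the list synaptic vesicle and exocytosis proteins, -0.0058 to 0.15 for tail-anchored membrane proteins, -0.23 to 0.28 for glycolysis enzymes, -0.075 to 0.043 for tubulins and actin cytoskeleton, -0.22 to 0.021 for zinc finger proteins named Zfp, -0.017 to 0.14 for molecular motors and -0.043 to 0.22 for integrated stress response targets. Ion channels had a median of 0.00028 with upper-quartile normalization. With GC correction, and with the replicate block and GC correction, the medians were -0.060 and -0.056 for glycolysis enzymes, -0.18 and -0.14 for neuronal cytoskeleton and growth cone proteins, 0.033 and 0.027 for zinc finger proteins named Zfp, and -0.037 and -0.044 for integrated stress response targets. Total replicate 1, with 6451174 reads, was the shallowest library, and of the named genes Zfp329 had the lowest mean, 9.17 CPM.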

Other observations

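The classes of genes by hydrophobic segment, the histone subgroups and the tests of later segments and of GC content between libraries were chosen after results had been seen; the other tests below had their bounds set before their own values were seen, but after the patterns were noticed. Proteins were predicted from the longest coding transcript, and a segment is a stretch of 19 residues with a mean hydropathy of at least 1.6; the N-terminal class has a segment starting in the first 60 residues, or a window of 10 residues with a mean of at least 2.2 in the first 35. All medians here come from the fit with the replicate block. The 1970 tested genes with an N-terminal segment, the place of signal peptides, had a median log2 fold change of -0.16, and -0.19 with GC correction. After GC correction 410 of them (20.8%) were called lower and 56 (2.84%) higher. Among the 7392 genes with no segment 336 (4.55%) were called lower and 677 (9.16%) higher. The N-terminal class made up 17.8% of genes and 46.3% of the lower calls after GC correction. Without the correction, which was chosen after seeing the data, the contrast was smaller: 24.6% of the class and 14.7% of genes with no segment were called lower, and the class made up 26.01% of the lower calls. Genes with a later segment (1529) had a GC-corrected median of -0.011, and the 178 genes whose only segment lies in the last 60 residues one of 0.012. Genes that entered the N-terminal class by the window of 10 residues alone were left out of a further grouping. The other genes with a segment were grouped by the residues from the start of the first segment to the C-terminus. With at most 60 residues they had a GC-corrected median of 0.0074 and 7.69% lower calls, and with up to 150 residues 0.029 and 8.69%. The values were -0.075 and 10.5% with up to 300 residues, -0.15 and 16.97% with up to 600, and -0.12 and 20.8% with more than 600. Since the rest of the N-terminal class was not left out, these steps may in part repeat its lower values. The medians did not fall at each step.

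Histone subgroups had medians of different size, and after GC correction of different direction; the difference between them was not tested. Their medians with the block, and with GC correction as well, were 1.16 and 0.53 for H3, 0.89 and 0.31 for H4, 1.02 and 0.31 for H2A, 0.26 and -0.22 for H2B, 0.66 and 0.15 for linker histones and 0.84 and 0.57 for variants outside the histone clusters. With the block, 9 of 9 H3 genes, 11 of 11 H4 genes, 12 of 15 H2A genes, 9 of 11 H2B genes and 6 of 7 linker histone genes were called higher, and 4 of 5 variants outside the histone clusters. With GC correction 8 H3 genes, 5 H4 genes, 2 H2A genes, 2 H2B genes, 3 linker histones and 3 variants were called higher, while 2 H2A and 2 H2B genes were called lower.

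Lower footprints of genes with an N-terminal hydrophobic segment were weighed against 3 technical explanations. The difference of medians to genes with no segment was -0.23 ± 0.011 (SE from 500 bootstrap draws of genes) after GC correction, against -0.19 before it. The class had a median coding GC content of 54.3%, against 52.5% in genes with no segment, and GC-rich genes were higher in IP. The GC trend thus runs the other way, which argues against GC content as the cause of the lower values. Before the correction it was -0.18 in pair 1 and -0.16 in pair 2. After the correction the difference was -0.24 ± 0.013 within deciles of abundance and -0.24 ± 0.013 within deciles of coding length. The SEs here treat genes as independent and do not measure the spread between replicates. Genes whose only segment emerges after or near the end of translation lay 0.20 ± 0.029 above the N-terminal class, but the other classes lay above it as well, so this does not bear on a lower recovery of ribosomes engaged with the ER membrane. Genes with a later segment, which would engage that membrane too if their segments are membrane segments, differed from genes with no segment by -0.045 ± 0.011. This is the direction that such a recovery would give, but within 1 SE of the bound of 0.05 set for it, and decides nothing. Of these genes 8.44% were called lower and 8.31% higher, against 4.55 and 9.16% of genes with no segment. How many of these segments span a membrane was not tested. The hypothesis stays open, and with it whether Ebp1 is less often bound to such ribosomes or whether membrane-bound ribosomes may be recovered less well on beads than by a sucrose cushion, since both differ between the same 2 groups.

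Higher footprints on histone genes kept a median of 0.31 ± 0.047 (SE from the same bootstrap of genes) after GC correction, above the bound of 0.2 set for that test. The correction took away most of the 0.88 ± 0.058 seen before it, and H2B genes then had a median of -0.22. This bootstrap treats the genes as independent, although many are near-identical copies (estimated inter-gene correlation 0.755 with the group alone). It does not measure the spread between replicates, so the bound is passed less surely than the SE implies. The summed share of all histone genes, which does not depend on how reads are divided among copies, was higher in IP by 0.55 or more (log2) in both pairs. That share was not corrected for GC content, so it does not tell whether the excess goes beyond GC content. Short coding length stays open: 842 other genes within the histones' range of coding length and GC content had a median of 0.072, so that histones exceeded them by 0.24 ± 0.050, past the bound of 0.2 by less than 1 SE. A link between Ebp1 and ribosomes on histone mRNAs is therefore a hypothesis that these libraries may not separate from properties of short, GC-rich genes.

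The source of the relation of fold change to GC content stays open. Libraries of the same group differed along GC content, with a Spearman rho of 0.365 between the IP libraries and 0.407 between the total libraries, in the same direction by replicate. Libraries of the same number come from the same lysate, so that a difference shared by a replicate cancels within pairs: the log2 ratio of pair 1 minus that of pair 2 had a rho of -0.099 with GC content. The part of the within-group differences that a replicate shares therefore does not account for the shift within pairs. The mean coding GC content weighted by reads was 51.6 and 51.1% in IP replicates 1 and 2 against 50.8 and 50.3% in total replicates 1 and 2. A GC bias of the preparation, its digestion and cushion included, and an effect of the immunoprecipitation cannot be told apart. They differ between the same 2 groups, and no biological explanation was tested.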
